A study of Mus musculus with 7 samples.

How the data were processed

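The series profiled single mouse zygotes with a combined assay that reads 1 histone mark by CUT&Tag and the full-length transcriptome from the same cell. CUT&Tag directs the Tn5 transposase to a histone mark with an antibody, so that the sequenced fragments lie at marked chromatin. Per the labels, the 7 samples comprised 2 batches with an antibody against H3K27me3 and 1 transcriptome sample made with them, and 2 batches with an antibody against H3K4me1 and their 2 transcriptome samples. Females were given 5 IU of pregnant mare serum gonadotropin and, 46 to 48 h later, 5 IU of human chorionic gonadotropin. Zygotes were collected at 23 after the second hormone, with no unit stated, and were freed of cumulus cells and zona pellucida. Each batch held the zygotes of 1 mouse. Only the H3K4me1 fragments were analysed here, and the H3K27me3 and transcriptome data were not used here.

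The deposited H3K4me1 table listed 1 fragment per line, with its position and the name of its zygote library. The last column of the deposited table was a count of 1 in all lines, so that it held no number of duplicate reads, and counts per region were made here by counting lines. The submitters' processing notes name the genome build mm10. The aligner, the removal of duplicates, the quality filters and any shift of the Tn5 cut sites are not given in the sources used here. Among 1424363 lines, 5 repeated another line of the same library with the same ends.

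Per the descriptions of both H3K4me1 samples, the table pooled both batches. Library names carry a number 4 or 5 after the word for the embryo, and the labels tie neither number to a batch. The table was therefore treated as 1 pooled sample, with no test between samples, no p-value from zygotes and no standard deviation. A library is named below by this number and its cell number, as in 5-4, and the values of libraries named 4 and of libraries named 5 are set side by side for lists that they move out of the central 95% of random lists, and for named genes whose intervals in the 2 sets do not overlap, a rule added after the data were seen. They are also given for the spermatid list and the oocyte and maternal-effect list, which were chosen after their values were seen. The 2 sets differ in depth, and those named 4 give few fragments per short gene. List medians of the 2 sets are therefore not compared as a difference in the mark.

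Gene positions and symbols came from RefSeq for GRCm38.p6, the assembly of mm10, with 49943 genes on chromosomes 1 to 19, X and Y. All members of the 10 gene lists were found by symbol, or by a synonym that named 1 gene, and members that resolved to the same gene were counted once. The imprinted Gnasas1, listed as neither protein-coding nor lncRNA, was left out. Strand and genome sequence were not used here. Windows around transcription start sites, CpG content and unsequenced bases, which the plan named, were therefore replaced after the data were seen. Gene levels were taken over the gene with 2.5 kb on each side, classes and profiles were taken around both ends of protein-coding genes, and random lists were matched on gene length. The rule that a named gene needs a window free of unsequenced bases could not be applied.

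Libraries with at least 5000 fragments on chromosomes 1 to 19, X and Y were kept. A fragment was placed by its midpoint. The level of a region is its fragments per bp over the mean per bp of the autosomes, which was 5.62 fragments per 10 kb in the pool, with chromosome lengths taken from the first to the last fragment. Intervals are exact 95% intervals, Poisson for levels and Clopper-Pearson for shares. They cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Where a gene is short, few fragments are expected, so that an interval above 1 is reached far more easily than an interval below 1, and counts of the 2 kinds are not a balance. Where a gene or stretch had 0 fragments, the level that 3 fragments would have given is printed as the limit. This limit is tighter than the upper end of the 95% interval used elsewhere, as for Ooep with 0.798 against 0.982.

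For each gene list, fixed before the data were examined, the median level was ranked among 10000 random lists of the same size, drawn within 10 groups of gene length, within protein-coding or lncRNA genes and within autosomes or X. The rank is given as a percentile and describes this pool. Bins of 10 kb at 3 times the autosomal mean or more, with at least 20 fragments from at least 5 libraries, were called enriched and merged with their neighbours into domains, and bins above 10 times the mean were listed apart. Agreement was taken as Spearman's rho across autosomal bins of 100 kb, between pairs of libraries thinned to 40000 autosomal fragments and between 2 random pools of 7 libraries drawn 20 times. After the data were seen, the pools of libraries named 4 and named 5 at equal depth were added, with 20 random splits into 3 and 11 libraries that left out the split by name. Bins and genes are not independent replicates. For the overlap of fragments within a library, each fragment was shortened by 10 bp at both ends.

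Genes were named by a rule written before the data were examined: the 3 highest and the 2 lowest members of each list, the 15 protein-coding genes with the highest level away from bins above 10 times the mean and with fragments from at least 5 libraries, and the 10 longest domains. Of the genes this rule names, 1 is not reported here. Other genes that are named were chosen after their values were seen. Members of multi-copy families, among them Zscan4, Obox, Usp17l, Tdpoz, Tcstv, Pramef, Trim43 and Duxf, are uncertain, because reads of near-identical copies may be placed at any of them or left out.

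The alternatives changed the minimum per library, the weight of each library, the deepest library, the bins above 10 times the mean, the position that stands for a fragment, the window around a gene, the bin size and the thresholds. Leaving out each library in turn, the split by library number, matching on local gene density (protein-coding genes within 500 kb), leaving out multi-copy families and leaving out bins with overlapping fragments were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

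The procedures were tested on simulated data. Poisson counts were drawn from the means of the real protein-coding genes with at least 10 fragments, and 200 of these genes were raised 3-fold. Of the raised genes, 100% had an interval above their unraised mean, and 96.1% of 14258 unraised genes had an interval that covered it. Since the intervals assume the same Poisson counts, this checks the computation only, and genes with fewer fragments were not covered. Of 200 random lists of 40 genes, 5% lay outside the central 95% of their random lists, and 97.5% did so when the list was raised 1.5-fold. Of 200 bins raised 5-fold among evenly filled bins, 95% were called, with 0 calls among 240109 others.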

Results

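H3K4me1, a histone mark found at enhancers and along active genes, was measured by CUT&Tag in single mouse zygotes. The table held 1424363 fragments from 16 zygote libraries, 5 of them named 4 and 11 named 5. Of these, 14 libraries reached 5000 fragments, 3 named 4 and 11 named 5, and together they held 1404305 fragments on chromosomes 1 to 19, X and Y. Depth ranged from 7106 fragments in library 5-11 to 197312 in library 5-4, with a median of 96240. The pool has no replicate, and all values below describe these 14 libraries.

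H3K4me1 fragments lay more often in and around protein-coding genes than between them. The level, taken as the share of fragments over the share of bases, was 1.24 (95% interval 1.23 to 1.25) at 1 to 5 kb from a gene end and 1.20 (1.19 to 1.21) within 1 kb of a gene end. The rest of the gene had a level of 1.14 (1.14 to 1.14), and intergenic sequence, which held 45.5% of fragments on 53.3% of bases, had a level of 0.854 (0.853 to 0.856). Unsequenced bases, and bases to which reads cannot be assigned, were counted among the bases, so that a class rich in them has a lower level. How much of the low intergenic level this gives was not tested. All 14 libraries had an intergenic level below 1, from 0.838 to 0.918. All 14 had levels above 1 in the rest of the gene and at 1 to 5 kb, and 13 had a level above 1 within 1 kb of a gene end, where libraries ranged from 0.979 to 1.35.

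**Figure D1:**
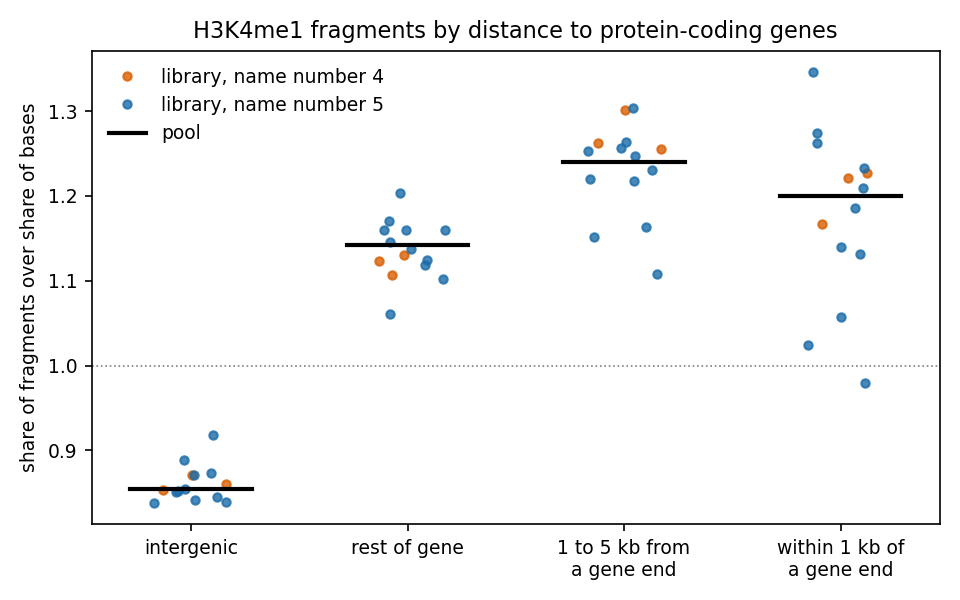
Share of H3K4me1 fragments over share of bases (vertical axis, no unit) in 4 classes of autosomal sequence, with the 14 libraries as points coloured by the number in their name and the pool as bars. Intergenic sequence sits at 0.854 in the pool and below 1 in all 14 libraries.

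No peak stood at gene ends. Around both ends of 13323 autosomal protein-coding genes of at least 10 kb, the level was 1.18 (1.16 to 1.20) in the steps of 100 bp centred within 250 bp of the end. It was 1.22 (1.21 to 1.23) on the outer side, between 500 bp and 2.5 kb away, and 1.27 (1.25 to 1.28) on the inner side. The centre thus lay at 0.949 times its shoulders (0.931 to 0.967, counting error of the centre only). Of the 13 libraries above 20000 fragments, 10 were lower at the centre than on the inner side. Start and end of transcription are averaged in this profile.

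Genes in gene-dense surroundings had higher levels of H3K4me1 fragments. No background control was used here, so the part of a level that does not come from the mark is unknown. The median level of autosomal protein-coding genes was 1.42 in the densest of 5 groups by the number of protein-coding genes within 500 kb and 1.01 in the sparsest. Summed over the genes of each group, the densest exceeded the sparsest in all 13 libraries above 20000 fragments, by 1.27 to 1.78 times. The median over 21631 protein-coding genes was 1.19 and that over 12697 lncRNA genes was 1.11. Of 20665 autosomal protein-coding genes, 6097 had an interval above 1 and 1482 had an interval below 1.

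Among the 10 gene lists, the oocyte and maternal-effect genes had the highest median level, 1.38 over 39 genes, which lay at percentile 86.2 of random lists. The intervals of 16 members lay above 1 and those of 2 lay below. Leaving out 1 library moved the rank from 66.0 to 95.6, and matching on gene density gave 69.3. In libraries named 5 the median of this list, 1.47, was also the highest. In those named 4 it was 1.12, below the 1.91 of the preimplantation lineage regulators. The highest members were Zp1, a zona pellucida glycoprotein, with a level of 2.99 (1.80 to 4.67), H1f8, the oocyte linker histone, with 2.76 (1.58 to 4.48), and Trim28, a corepressor that protects imprints, with 2.70 (1.60 to 4.26). At the other end, Ooep of the subcortical maternal complex had 0 fragments, which allows a level of up to 0.798. Btg4, which acts in the clearance of maternal mRNA, had a level of 0.547 (0.220 to 1.13).

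The zygotic genome activation genes had the lowest median level of the lists, 0.960 over 38 genes, at percentile 3.32 and inside the central 95% of random lists. It fell to percentile 0.69 with libraries weighted equally, 1.53 without the deepest library 5-4, and 1.06 with 5 kb around the gene, and rose to 9.82 both with 1 kb around the gene (median 1.02) and over the gene body (median 1.02). Without library 5-5, 5-6, 5-8 or 5-1 it was 0.75, 1.27, 1.37 or 1.39, all below the central 95%. In libraries named 4 the median was 0.400, at percentile 0.98, and in those named 5 it was 1.01, at 8.69. The libraries named 4 gave few fragments per short gene of this list, with 1 at Duxf3 and 2 at Tdpoz4. The 2 medians therefore do not measure a difference in the mark. Among random lists that were also matched on local gene density the pooled median of the list lay at percentile 16.6. The intervals of 8 members lay above 1 and those of 2 lay below. Summed over its genes the list had a level of 1.24, above the cumulus (1.05), spermatid (1.09), imprinted (1.10), mammary (1.11) and blood cell (1.21) lists, so that it was the lowest by the median only. With 1 kb around the gene and over the gene body, the median of the spermatid genes, given below, was lower than that of this list. Duxf3, a copy of the transcription factor Dux that switches on genes of the 2-cell embryo, had a level of 5.39 (3.52 to 7.90), Tdpoz4 had 3.78 (2.01 to 6.47) and Usp17la had 2.51 (1.40 to 4.13). Zscan4f, of a family expressed in the 2-cell embryo, and Gm4340 had 0 fragments, which allows levels of up to 0.568 and 0.713. Of the 38 genes, 21 belong to multi-copy families, whose reads may be shared between copies, and the other 17 had a median of 0.999 at percentile 10.5.

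The preimplantation lineage regulators had a median level of 1.27 over 25 genes, at percentile 46.8, with 6 intervals above 1 and 0 below. Fgf4, a growth factor of the inner cell mass, had a level of 2.61 (1.39 to 4.46), Tfap2c, a trophectoderm factor, had 2.58 (1.68 to 3.78), and the pluripotency factor Nanog had 2.49 (1.45 to 3.99). Sox2 had 1 fragment and a level of 0.238 (0.00603 to 1.33), and Gata6, a factor of the primitive endoderm, had 0.653 (0.357 to 1.10). In the libraries named 4 alone the median was 1.91, at percentile 99.6, and in those named 5 it was 1.15, at 21.3. Matching on gene density moved the rank to 94.0, and leaving out library 4-2 moved it to 23.5.

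Polycomb-target developmental regulators had a median level of 1.16 over 40 genes, at percentile 27.3, with 8 intervals above 1 and 1 below. The rank was 82.8 with matching on gene density and 4.28 without library 5-2. Pax7, a factor of muscle stem cells, had a level of 2.40 (2.02 to 2.84), Tbx5, a factor of heart and forelimb, had 2.22 (1.84 to 2.66), and En1 had 2.20 (1.17 to 3.77). Hoxb1 had 0 fragments, which allows a level of up to 0.711, and Hoxd13 had 1 fragment and a level of 0.212 (0.00538 to 1.18). Housekeeping genes had a median of 1.26 over 40 genes, at percentile 59.55, with 11 intervals above 1 and 1 below, and leaving out 1 library moved this rank from 42.6 to 85.1. Cox4i1 of the respiratory chain had a level of 3.24 (1.98 to 5.00), the ribosomal protein gene Rpl3 had 3.18 (1.92 to 4.97) and the proteasome gene Psmd4 had 2.98 (1.93 to 4.40). The level of Rpl3 was 9.39 (4.50 to 17.3) in libraries named 4 and 1.83 (0.839 to 3.48) in those named 5. The splicing factor gene Srsf1 had 0.145 (0.00367 to 0.809) and the translation factor gene Eif4a1 had 0.339 (0.0411 to 1.23).

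Imprinted genes, expressed from the copy of 1 parent, had a median level of 1.15 over 35 genes, at percentile 52.4, with 10 intervals above 1 and 4 below, and leaving out 1 library moved the rank from 40.7 to 78.4. Ascl2 had a level of 2.63 (1.31 to 4.70), Gab1 had 1.98 (1.66 to 2.35) and Phlda2 had 1.89 (0.759 to 3.89). Both Peg3, with 0.338 (0.124 to 0.736), and Snrpn, with 0.459 (0.381 to 0.548), lay below the autosomal mean. Snrpn rests on 122 fragments from 13 libraries, and its level was 0.211 (0.101 to 0.388) in libraries named 4 and 0.513 (0.422 to 0.617) in those named 5.

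Markers of other cell types stayed within the central 95% of random lists, and their ranks moved with single choices. Cumulus and granulosa cell markers, the cells that surround the egg, had a median of 1.10 over 30 genes, at percentile 9.24, with 9 intervals above 1 and 3 below. The rank was 35.9 with matching on gene density, 3.76 with 5 kb around the gene and 4.54 without library 5-9. Amh had a level of 2.63 (1.31 to 4.71), Hsd17b1 had 2.60 (1.34 to 4.54) and Inha had 2.15 (1.03 to 3.95), while Areg had 0.257 (0.0312 to 0.929) and Ptx3 had 0.326 (0.0395 to 1.18). Spermatid genes had a median of 1.24 over 30 genes, at percentile 82.7, with 5 intervals above 1 and 1 below. With 1 kb around the gene the median was 0.918 at percentile 12.03, over the gene body it was 0.940 at 13.1, and the rank was 86.3 in libraries named 4 and 29.3 in those named 5. The testis kinase genes Tssk2 and Tssk1, which lie side by side, had levels of 3.34 (1.73 to 5.84) and 3.31 (1.71 to 5.78), and Ldhc had 1.87 (1.19 to 2.81). The windows of Tssk2 and Tssk1 overlap, so that their levels can count the same fragments and are not 2 separate results. Hspa1l had 0.309 (0.0374 to 1.12) and Acrv1 had 0.502 (0.104 to 1.47).

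Mammary epithelial markers had a median of 1.23 over 25 genes, at percentile 45.8, with 6 intervals above 1 and 2 below, and over the gene body the rank was 75.6. The milk protein gene Wap had a level of 3.48 (1.99 to 5.66), Ly6a had 2.40 (1.20 to 4.29) and Elf5, also a trophectoderm factor, had 2.19 (1.64 to 2.86). The casein gene Csn3 had 0.149 (0.00376 to 0.828) and Foxa1 had 0.287 (0.0347 to 1.04). Blood cell markers had a median of 1.27 over 20 genes, at percentile 73.8, with 5 intervals above 1 and 1 below. Without library 5-6 the median was 1.01 at percentile 20.1, and matching on gene density gave 51.2. The T cell gene Cd3e had a level of 2.68 (1.72 to 3.99), the myeloid factor gene Spi1 had 2.41 (1.80 to 3.16) and Nkg7 had 2.04 (0.820 to 4.20). The globin gene Hbb-bt had 0.556 (0.0673 to 2.01).

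**Figure D2:**
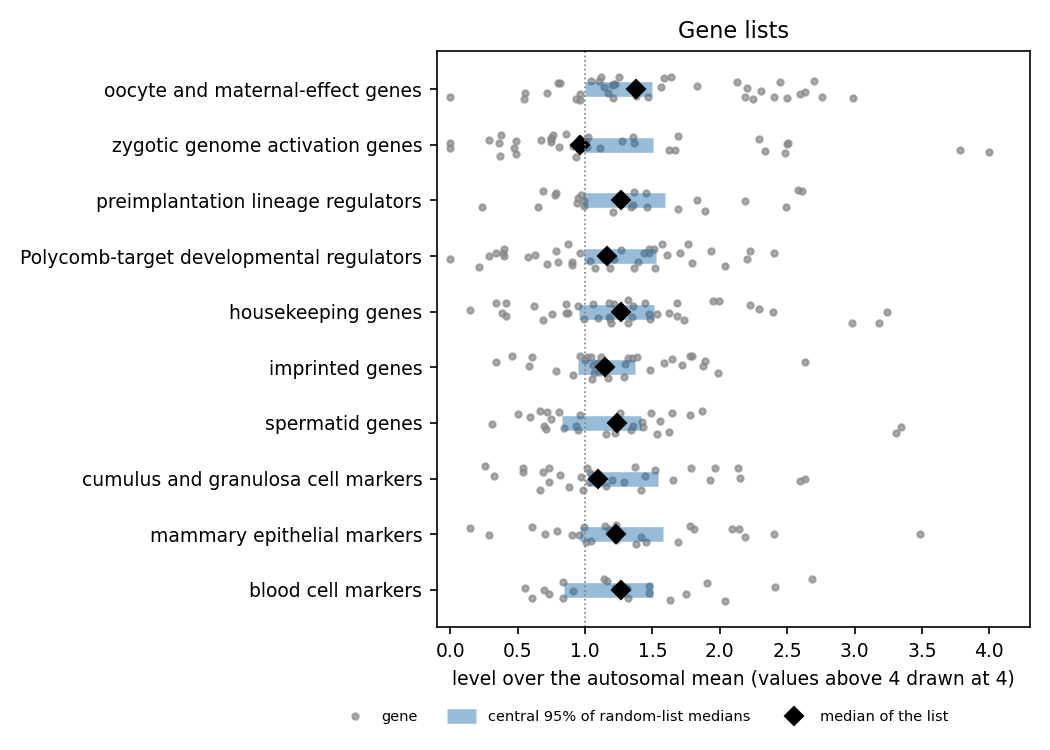
Levels of the genes of the 10 lists over the autosomal mean (horizontal axis, no unit), with genes as grey points, medians as black diamonds and the central 95% of medians of random lists as blue bars. With 2.5 kb around the gene, the zygotic genome activation genes have the lowest median, 0.960, and the oocyte and maternal-effect genes the highest, 1.38. Both places change with the window or the libraries used. All 10 medians lie within their bars.

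The 15 protein-coding genes with the highest levels were led by Gm6408 on chromosome 5 (146481943 to 146484702), with 6.42 (4.27 to 9.28). Next came Psmb8, a subunit of the immunoproteasome, on chromosome 17 (34198195 to 34201454), with 6.25 (4.18 to 8.97) from 29 fragments of 11 libraries. The zygotic factor gene Duxf3 on chromosome 10 (58229505 to 58233089) followed, and LOC100504180, which lies beside it, had 4.43 (2.74 to 6.78). With 2.5 kb on each side the windows of these 2 genes overlap, so that their levels can count the same fragments. The list held 2 genes of the C/EBP transcription factors, Cebpe with 4.96 (2.99 to 7.75) and Cebpb with 4.64 (2.70 to 7.43). It also held Hjurp, the chaperone that loads the centromeric histone CENP-A, with 4.86 (3.75 to 6.20) from 65 fragments, Sox8 with 4.72 (3.09 to 6.92), Gpihbp1 with 4.59 (2.68 to 7.36) and Gm6370 with 4.57 (2.79 to 7.06). The remaining genes were Cstad with 4.42 (3.25 to 5.88), the iron-sulfur scaffold gene Iscu with 4.42 (2.91 to 6.43), Gngt2 with 4.37 (2.74 to 6.61), Gm30191 with 4.36 (2.67 to 6.74) and Ogfr with 4.36 (2.90 to 6.30). Duxf3 belongs to a multi-copy family, whose reads may be shared between copies. Gm6370 lies close to Gm6408 on chromosome 5 (146491357 to 146494136). Whether these 2 genes, LOC100504180 or others of the 15 have near-identical copies was not tested. The level of Sox8 was 12.2 (6.32 to 21.4) in libraries named 4 and 3.09 (1.69 to 5.19) in those named 5. Of the 64 named genes, 41 had levels more than 1.5 times apart between these sets, and 3 of them, Sox8, Rpl3 and Snrpn, had intervals that did not overlap.

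Enriched sequence was found in short stretches. In all, 1221 bins of 10 kb were enriched, against 0.492 bins that counting error alone would give with evenly spread fragments, and they held 1.98% of all fragments. Fragments are not evenly spread, and where the level is higher, counting error gives more such bins than in the even case. The enriched bins merged into 1129 domains, 1053 of them 1 bin long and 11 of them at least 3 bins long. A protein-coding gene overlapped 69.0% of enriched bins (66.3% to 71.5%) and 46.5% of all bins (46.3% to 46.7%). Chromosome 11 held 91.7 enriched bins per 100 Mb, chromosome 4 held 87.4, chromosome 3 held 15.3 and chromosome X held 4.17. The threshold is set on the autosomal mean, so that bins of X, with its level of 0.554, reach it less easily. Bins called in the libraries named 5 alone, 312 on the autosomes, had a level of 3.48 (3.28 to 3.70) in the libraries named 4, which had no part in the call. The number of enriched bins depends on depth: leaving out library 4-5, 5-2, 5-3, 5-4, 5-5, 5-6, 5-7 or 5-10 gave 757, 738, 812, 553, 734, 658, 622 or 685 bins.

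The longest domain lay on chromosome 1 over the genes Mroh2a, Hjurp and Trpm8, the last of them a cold-sensing ion channel. The bins called there ran from 88250001 to 88310000, with a level of 4.98 (4.26 to 5.79) from 168 fragments of 13 libraries. The bin before it, inside Mroh2a, reached 11.9 times the autosomal mean. From 88230001 to 88310000, a stretch of 80 kb chosen after its values were seen, the level was 6.41 (5.69 to 7.19) from 288 fragments. All 13 libraries above 20000 fragments had an interval above 1 there, with levels from 3.52 in library 5-2 to 8.30 in library 5-4. Library 5-11 had 0 fragments, which allows a level of up to 13.3. No library had more than 3 fragments over the same base.

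**Figure D3:**
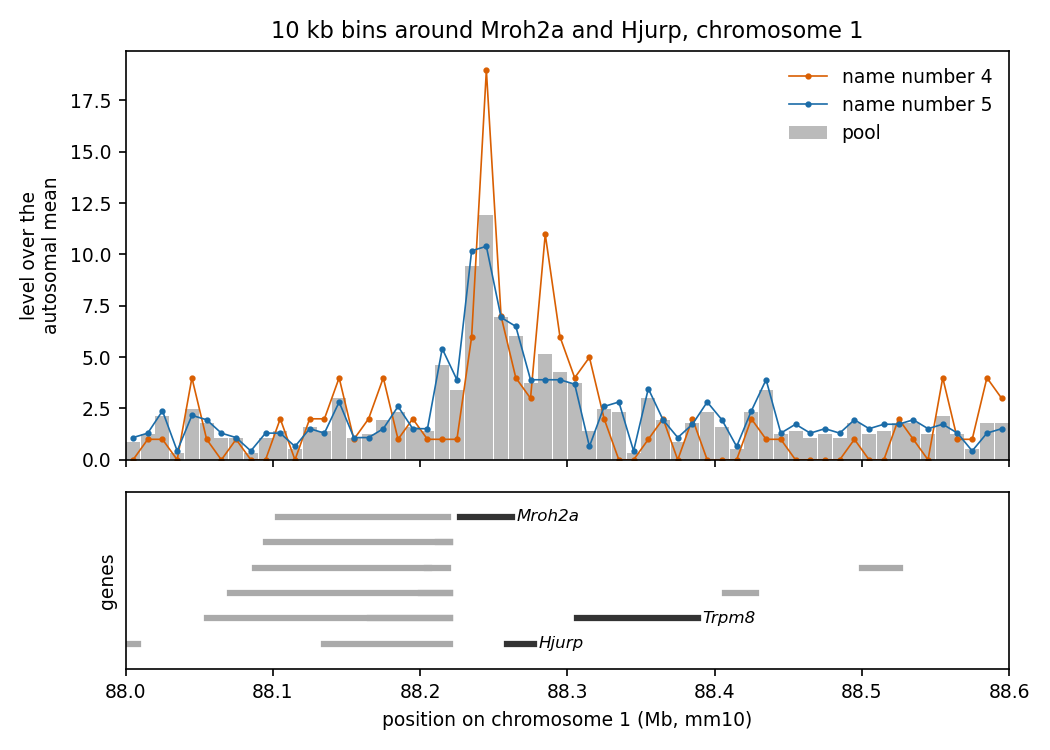
Levels of 10 kb bins over the autosomal mean (upper panel, vertical axis) along part of chromosome 1 in mm10 (horizontal axis), with the pool as bars and the libraries named 4 and 5 as lines, above the protein-coding genes (Mroh2a, Hjurp and Trpm8 in black). The bin inside Mroh2a reaches 11.9 in the pool and 10.4 in libraries named 5, and lies higher in libraries named 4.

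The next longest domains were 40 kb each, at Grhl3 on chromosome 4 (135550001 to 135590000) with a level of 4.00 (3.22 to 4.92) and at Elfn2 on chromosome 15 (78680001 to 78720000) with 3.87 (3.10 to 4.77). Grhl3 encodes a factor of epidermal differentiation. The others were 30 kb long. They lay at Sfi1 on chromosome 11 with a level of 6.70 (5.52 to 8.06), near the start of chromosome 9 (3040001 to 3070000) with 5.28 (4.24 to 6.50) and no gene, and at Niban2 on chromosome 2 with 4.69 (3.71 to 5.84). Sspo on chromosome 6 had 4.51 (3.55 to 5.64), Arrb1 on chromosome 7 had 4.33 (3.39 to 5.44), Fam78a on chromosome 2 had 4.09 (3.18 to 5.18), and Slit3 on chromosome 11, an axon guidance gene, had 3.85 (2.98 to 4.91). The domain at Sfi1 had up to 5 fragments of 1 library over a base. Close to the domain of chromosome 9, the bin from 3020001 to 3030000 lay at 11.6 times the mean, with up to 6 such fragments. Sequence held in extra copies therefore stays open for both domains.

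A further 34 bins lay above 10 times the mean, and 32 of them held fragments of all 14 libraries. The highest lay on chromosome 13 (13860001 to 13870000), at 104 times the mean and with no gene, followed by a bin at Tmem196 on chromosome 12 (120020001 to 120030000) at 91.8 times the mean. A protein-coding gene overlapped 10 of the 34, among them Hsd11b1, a glucocorticoid-activating enzyme, at 35.9, Abhd6 at 31.1, Lama1 at 17.3 and Col4a6 at 22.1 times the mean. In 33 of the 34 bins at least 1 library had more than 4 fragments over the same base, and in 27 more than 7. The counts were 82 and 3 among the 1221 enriched bins, which hold fewer fragments and so can stack less.

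**Figure D4:**
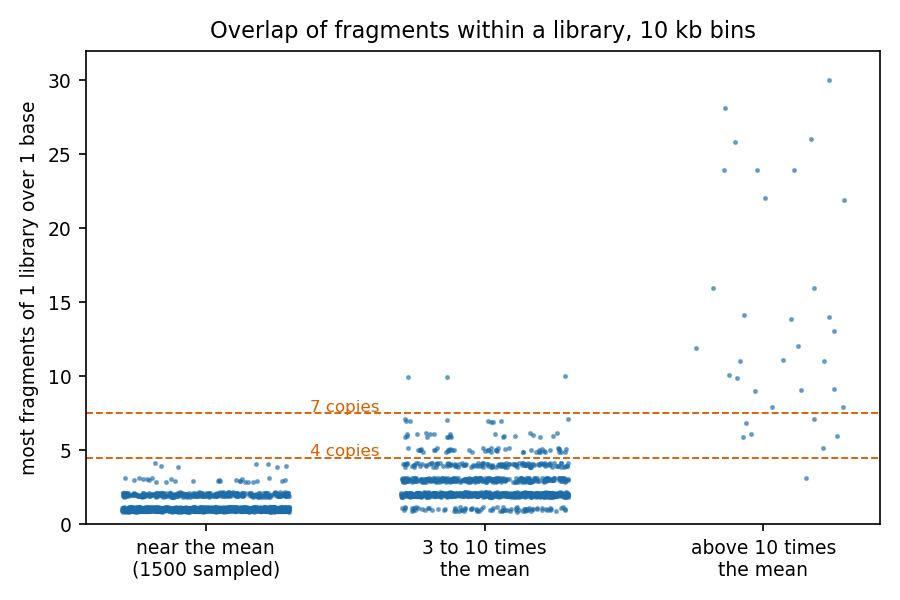
The most fragments of 1 library over the same base (vertical axis) in 3 sets of 10 kb bins, 1 point per bin with a small random offset and dashed lines just above 4 and 7 copies. Of the bins above 10 times the mean, 33 lie above the lower line, while bins near the mean hold too few fragments per library to be a contrast.

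Chromosome 11 had the highest level of the autosomes, 1.21 (1.20 to 1.22), followed by chromosome 9 with 1.10 (1.09 to 1.11) and chromosome 19 with 1.08 (1.07 to 1.09). Chromosome 3 was lowest with 0.866 (0.859 to 0.872), and chromosome 14 had 0.886 (0.879 to 0.893). Chromosome 11 carries 13.5 protein-coding genes per Mb and chromosome 3 carries 6.26, while chromosome 7, with the most, 14.3, had a level of 1.06 (1.05 to 1.06). Chromosome 11 lay above 1 and chromosome 3 below 1 in all 14 libraries, from 1.07 to 1.32 and from 0.748 to 0.907. The X chromosome had a level of 0.554 (0.549 to 0.558) and the Y chromosome 0.0280 (0.0265 to 0.0295).

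X and Y levels differed between libraries. Outside the bins above 10 times the mean, the Y level was 0.0853 (0.0749 to 0.0968) in library 5-8, 0.0821 (0.0751 to 0.0896) in library 5-6 and 0.0634 (0.0570 to 0.0703) in library 5-7. Their X levels were 0.213 (0.200 to 0.225), 0.265 (0.255 to 0.274) and 0.316 (0.305 to 0.327). The X levels of the other 11 libraries ran from 0.529 in library 5-3 to 0.763 in library 5-1. Their Y levels ran from 0.000519 in library 5-2 to 0.0126 in library 5-11, on 2 to 16 fragments. Mitochondrial fragments made up a median of 0.789% of a library and a lowest of 0.167%. Library 5-11 had the highest share, with an interval from 10.3% to 11.7%, and library 5-1 had 4.89% (4.73% to 5.06%).

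**Figure D5:**
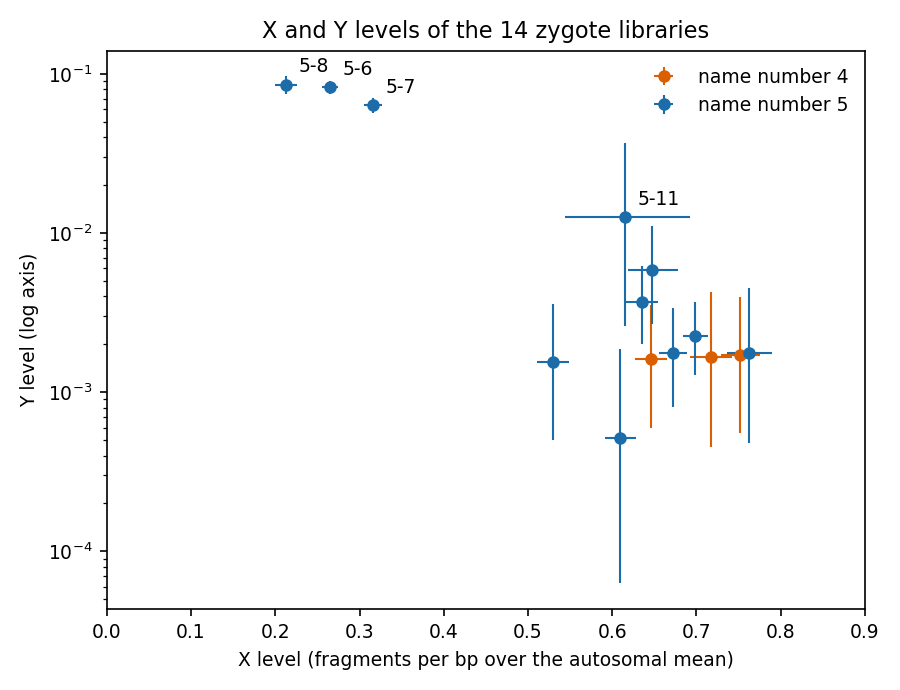
X level (horizontal axis) and Y level (vertical log axis) of the 14 libraries, as fragments per bp over the autosomal mean, without bins above 10 times the mean, with 95% Poisson intervals as bars and colours by the number in the library name. Libraries 5-6, 5-7 and 5-8 have Y levels of 0.0634 to 0.0853 and X levels of 0.213 to 0.316.

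Zygotes agreed in the broad distribution of fragments and little in the fine one at this depth. Across 100 kb bins, thinned to 40000 fragments, the 78 pairs of 13 libraries had a median rho of 0.182, from 0.139 to 0.229. Pairs of libraries named 4 had a median of 0.172, pairs named 5 had 0.183, and pairs with 1 library of each had 0.180. Pools of 7 libraries had a median rho of 0.767, from 0.749 to 0.775 over 20 draws. Pools of the libraries named 4 and named 5, at 240753 fragments each, had a rho of 0.542, and 20 random splits into 3 and 11 libraries at that depth had a median of 0.580, from 0.548 to 0.594. Across 1 Mb bins the medians were 0.573 for pairs and 0.944 for pools. Across 10 kb bins they were -0.00335 and 0.291, and the mean of 5.62 fragments per 10 kb over 14 libraries leaves most bins of a single library empty.

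Fragment lengths showed steps of the nucleosome. After smoothing over neighbouring lengths, the length distribution had peaks at 210, 364 and 520 bp, and the median was 322 bp. Counts fell from 1165 fragments at 602 bp to 5 at 603 bp, the longest length. The median and the shares below therefore describe fragments up to that length only. Short fragments also stood in narrow peaks, as with 837 at 57 bp and 125 at 56 bp. Fragments of 150 to 250 bp made up 27.9% (27.8% to 27.9%) and those of 300 to 500 bp 40.8% (40.7% to 40.9%). Fragments of 100 bp or less made up 3.07% (3.04% to 3.10%), from 2.30% to 10.5% per library.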

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

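All tests in this part except the share of near-copies (without its random shifts) and the chromosome 13 ratio were chosen only after the result was seen, and the design names no groups among these libraries. Extra copies of chromosome 13 and a Y chromosome were tested for library 5-11, and no biological explanation was tested for the other patterns. Signal outside the chromosomes and libraries used above was found in 4 places. Mitochondrial DNA held 16403 fragments over all libraries. The unplaced contig JH584304 held 1924 fragments. Library 4-1 had 674 fragments and library 4-3 had 68, both under the minimum of 5000.

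A zygote after replication holds 4 copies of a locus, and 7 with both polar bodies, so that fragments over a base cannot exceed this at a single-copy locus if each stands for 1 molecule. In 27 of the 34 bins above 10 times the autosomal mean a library had more than 7, which argues against single-copy loci there and may come from sequence held in more copies than the assembly shows. These bins held 0.137% of library 5-6, 0.270% of the deepest library 5-4, 1.01% of library 5-9 and 7.33% of library 5-11, the shallowest kept. The shares in the other kept libraries lay between 0.241% and 0.745%. The libraries left out, 4-1 and 4-3, had 7.59% and 29.4%. Fragments in these bins therefore did not rise in step with depth. Extra copies alone would give a similar share in each library, so these shares argue against them as the whole cause. What else adds fragments there was not tested beyond the near-copies below. Of the fragments in these bins, 30.1% had another fragment of their library within 5 bp at both ends, against 17.0% (15.95 to 18.3 over 20 draws) after each fragment was shifted at random by up to 100 bp, so that near-copies of the same amplified molecule could add to such stacks, but local density alone gives part of the share. After such fragments were merged, 24 of the 34 bins still had more than 7, which argues against near-copies as the whole cause of the stacks. The 80 kb at Mroh2a and Hjurp had no stack over 3, but at this depth a modest gain in copies would give none either, so that extra copies of that stretch stay open.

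Library 5-11, the shallowest kept, differed from the other libraries beyond its counting interval on 11 of 19 autosomes, among them chromosome 13 at 1.61 (1.46 to 1.76), chromosome 12 at 1.26, chromosome 1 at 0.751 and chromosome 14 at 0.718. Its Y level of 0.106 with all fragments was the highest, but only 3 of its 27 Y fragments lay outside bins above 10 times the mean, and there the upper end of the interval, 0.0368, lay below the 0.0634 of library 5-7, which argues against a Y chromosome in this zygote. The window of chromosome 13 from 50 to 60 Mb, chosen among windows with enough fragments after a window with 3 fragments had come first, had a ratio of 3.10, and without it the ratio was 1.43 (1.29 to 1.59), which argues against a pile of fragments there as the whole cause. Extra copies were predicted to give 1.5 or more, which the 1.61 meets and the 1.43 and the median window of 1.302 do not. Extra copies therefore stay open, as does uneven recovery of 7106 fragments, since 10 Mb windows of this library vary by 0.547 (SD over windows) where counting error gives 0.198.

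Library 5-1 had 0.679 times the chromosome 14 share of the other libraries. Counting error is argued against by the upper end of the interval, 0.710. All 13 windows of 10 Mb lay below 1, which argues against a few low stretches as the cause. Of 247 combinations of library and chromosome, 7 with at least 10 windows had all windows on the same side of 1, so that chromosome-wide shifts were not peculiar to this one, and uneven recovery of whole chromosomes and a lower copy number both stay open.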

How the results depend on the processing

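The split by library name number, leaving out each library, matching on gene density, leaving out multi-copy families and the chromosome alternatives were chosen only after the data were seen. Of 366 alternatives, counted without settings that repeat another, 310 left the value within its 95% interval, its side of the central 95% of random lists, or 1.5 times its count. For list percentiles, 223 of 232 stayed on their side, and the exceptions were the zygotic list and, in libraries named 4, the preimplantation list. This count does not show stable ranks, since a rank can move far inside the central 95%. The Polycomb list ran from 4.28 to 82.85 and the spermatid list from 12.03 to 90.75 without leaving it. For 64 named genes, 2 of 128 values left their counting interval. The cause of the changes below was not tested, except that the minimum of 20 fragments lies above 3 times the mean, so that fewer libraries give fewer enriched bins by construction.

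With libraries weighted equally, the class levels were 0.861 (intergenic), 1.14 (rest of gene), 1.23 (1 to 5 kb) and 1.18 (within 1 kb), chromosome 3 was 0.853, X was 0.580 and the zygotic list lay at percentile 0.69. Without the deepest library, the rest of the gene was 1.15, 1 to 5 kb 1.23, within 1 kb 1.18, the zygotic list 1.53 and enriched bins 553. Without bins above 10 times the mean, intergenic sequence was 0.851 and the rest of the gene 1.15. In libraries named 4, the levels were 0.861, 1.12 and 1.28 for intergenic, rest of gene and 1 to 5 kb, 1.27 for chromosome 11, 0.855 for chromosome 3 and 0.699 for X, with the zygotic list at 0.98 and the preimplantation list at 99.6. In libraries named 5, the rest of the gene was 1.15, 1 to 5 kb 1.23, chromosome 11 1.20, X 0.522 and enriched bins 315. This set holds libraries 5-6, 5-7 and 5-8, whose X levels of 0.213 to 0.316 outside bins above 10 times the mean lower its X level. The other libraries named 5 ran from 0.529 to 0.763 there, and those named 4 from 0.646 to 0.752. Fragments of 150 to 250 bp gave 0.858 (intergenic), 1.23 (1 to 5 kb), 1.15 (within 1 kb) and 0.885 for the centre of gene ends over its shoulders. With 5 kb around the gene the zygotic list lay at 1.06. Enriched bins numbered 59 with 5 kb bins, 81 at 5 times the mean and 3579 with 10 fragments or more. Spearman's correlation between libraries was 0.573 in 1 Mb bins and -0.00335 in 10 kb bins, and between pools 0.944 and 0.291. Leaving out each library gave 0.851 to 0.856 (intergenic), 1.14 to 1.15 (rest of gene), 1.23 to 1.25 (1 to 5 kb), 1.18 to 1.22 (within 1 kb), 0.75 to 9.06 (zygotic list) and 553 to 1187 (enriched bins). The zygotic list without multi-copy families lay at percentile 10.5, and at 8.38 when the Pramel genes were at first not counted among them.

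A minimum of 1000 kept the same 14 libraries and tests nothing. Windows around transcription start sites, CpG-rich against CpG-poor promoters, matching on CpG content, weighting by duplicates, enriched bins in libraries named 4 alone, agreement between batches and leaving out a replicate were not run. No paired analysis was possible because the library names do not name the batch, and no test between samples was run.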

Other observations

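Median levels differed between families of genes that share a symbol stem, and these 51 families were chosen after the data were seen. The median lay below the central 95% of random lists matched on gene length in 7 families and above it in 4. The counts were 9 and 4 when the lists were also matched on local gene density. With independent members, 2.55 families in all would lie outside. Members of a family that lie side by side are not independent, so that the excess over 2.55 is no test of a difference. The vomeronasal receptor genes (Vmn, 354 genes) had a median level of 0.443 and the olfactory receptor genes (Olfr, 1104 genes) one of 0.597, both lower than all 10000 random lists matched on gene length. Of the Vmn genes, 85 had an interval below 1 and 2 above, and of the Olfr genes 20 below and 31 above, where most genes are too short for an interval below 1. The Pramel genes, 45 in number, had 0.632, with 16 intervals below 1 and 3 above. The zinc finger genes (Zfp, 388 genes) had 1.04, also lower than all random lists, with 45 intervals below 1 and 53 above, and the Adam protease genes, 34 in number, had 0.884 at percentile 0.11, with 4 below and 6 above. The Cd genes, 98 in number, had 1.08 at percentile 0.68, with 2 below and 22 above, and the Clec lectin genes, 33 in number, had 1.00 at percentile 1.16, with 1 below and 2 above. At the other end stood the solute carrier genes (Slc, 362 genes) with 1.39 at percentile 99.97, 142 intervals above 1 and 20 below, and the collagen and related genes (Col, 42 genes) with 1.49 at percentile 99.98, 24 above and 5 below. The genes with the stem Sh, 35 in number, had 1.55 at percentile 99.8, with 22 above and 0 below. Keratin genes (Krt, 53 genes) had 1.62 at percentile 98.72, with 20 above and 0 below, and at 66.94 among random lists that were also matched on local gene density. How reads that fit several near-identical genes were placed is not given, and its effect on these families was not tested.

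Autosomal shares differed between zygote libraries by more than counting error. Counting error does not cover uneven recovery, so that this excess alone says nothing of copy number. Over 247 combinations of 13 libraries and 19 autosomes, the share over the other libraries ran from 0.679 to 1.17, and 220 lay between 0.9 and 1.1. Chromosome 19 was at 0.723 in library 5-2 and 0.761 in library 4-5, and chromosome 2 was at 1.17 in library 4-2.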
